A study of Mus musculus with 12 samples.

How the data were processed

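RNA from mouse bone marrow mesenchymal stem cells (MSCs) grown in DMEM with 10% FBS was extracted with Trizol and sequenced as BGISEQ-500 libraries, per the labels' protocols. The labels place 12 libraries in 3 groups, which are young vehicle (replicates 2, 4 and 5), old vehicle (replicates 1, 2, 3, 5, 8 and 9) and old melatonin (replicates 1, 3 and 5, 1 µM for 24 h). Replicate numbers are those of the library titles. The libraries came in 2 tables. The age table holds the young libraries with old vehicle replicates 2, 8 and 9, and the melatonin table holds the melatonin libraries with old vehicle replicates 1, 3 and 5.

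Each table deposited by the authors lists 18908 genes by symbol and gene identifier, with an estimated count, an FPKM and a TPM per library, per the file headers. The estimated counts deposited by the authors need not be whole, and 67.7% of them lay within 0.005 of a whole number. The FPKM values deposited by the authors are scaled for gene length and library size, and the TPM values deposited by the authors are scaled to a common total per library, as the units are defined. The submitters' processing notes name RSEM, Bowtie2, BWA and the mm39 build, with no roles or versions, so the strand setting and the annotation are not given in the sources used here. The tables carried no fold changes or p-values that were used here. Count columns whose headers spell vehicle as Vel were assigned to the titles with the same letter and number. Over genes with counts of at least 500, the FPKM and the TPM column of a title best fitted the count column of the same title in 12 of 12 libraries. All tests used the estimated counts, and FPKM and TPM served only for this check. The mouse reference held for this work is of another build than the one in the processing notes, so gene positions were not used here. Mitochondrially encoded genes and Xist were not analysed here.

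Estimated counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr with a minimum count of 10 and a minimum total of 15. Each table was normalized by TMM and tested alone with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) at a Benjamini-Hochberg adjusted p under 0.05. Changes are log2 fold changes with their standard error (SE), as old minus young or as labelled melatonin minus old vehicle. Gene levels in the comparisons are CPM (counts scaled by library size), here with TMM-scaled sizes, given as mean ± SD with n = 3 libraries per group. Levels compared between libraries of both tables are CPM with TMM scaling over all 12 libraries, on which 3 counts, the most that a count of 0 allows, equal 0.136 to 0.152 CPM. These limits cover counting error only. The smallest p of an exact two-sided permutation test of 3 libraries against 3 is 0.1.

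Gene lists were tested with limma's camera (limma 3.58.1) on voom values with a preset inter-gene correlation of 0.01. P-values were adjusted over the 26 lists with at least 5 tested genes, out of 32 lists of cell type markers and pathways. Each list was tested again with its estimated correlation, and with fry, which asks whether the genes of a set move, without comparing the set with other genes. The mean log2 CPM of a list used a prior count of 2. The groups, the tests, the lists, the alternatives that are not named as added, and the rule for named genes were fixed before the data were examined. By that rule the text names 11 genes always, which are Nsd2, Runx2, Sp7, Alpl, Bglap, Pparg, Cdkn1a, Cdkn2a, Trp53, Mki67 and Lmnb1. Where no gene passed in a direction, it names the 5 with the smallest p among annotated genes with separated groups and a level above the median. It also names up to 4 members of each list described, those with the smallest p. Some genes that the rule takes are not reported here, and none was put in their place. Genes given to characterise the match of single libraries were chosen after their values were seen.

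Libraries of the 2 tables were compared by Pearson r of log2 CPM over 12691 genes and each was matched to the library of the other table with the highest r. Counting error within a matched pair was assessed by a chi-square of both counts of each gene, whose median over genes was divided by the median expected from counting error alone. Differences within matched pairs were tested with edgeR, with the pair as a block. The alternatives were DESeq2 1.42.0 size factors and its Wald test, no filter on low counts, an adjusted p under 0.1, an absolute log2 change above 1, all old vehicle libraries against young, the label number as a block, an estimated correlation, and leaving out each library. Limma-voom, a covariate for macrophage transcripts (the mean log2 CPM of the macrophage list), the removal of the 2 libraries richest in them, and leaving out libraries for lists and for the agreement of both comparisons were added after the data had been seen. Removing those 2 libraries left a lone old vehicle library in each comparison. The list fits of these added settings used the preset correlation only.

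The steps were tested on simulated counts drawn from the means and library sizes of the real genes, with the spread of the real libraries. In the age simulation of 13372 genes, edgeR recovered 1.52% of genes changed 2-fold, 31.8% of those changed 4-fold and 72.7% of those changed 8-fold, with 3 false calls among 73. DESeq2 recovered 3.03%, 75.8% and 90.9% of them, with 83 false calls among 195. For limma-voom the shares were 0%, 28.8% and 66.7%, with 5 false calls among 68. In the melatonin simulation of 13312 genes, edgeR recovered 0%, 32.3% and 66.7%, with 2 false calls among 67. DESeq2 recovered 8.96%, 81.5% and 86.4% there, with 82 false calls among 198, and limma-voom 0%, 30.8% and 66.7%, with 3 among 67. Camera called the planted list and 0 others in both simulations. Genes were drawn independently of each other there, so these runs cannot show how often camera calls lists of correlated genes wrongly. The matching step joined 6 of 6 simulated cultures to their own second library.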

Results

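Gene expression was measured by RNA sequencing in cultured mouse bone marrow MSCs, the marrow cells that can form osteoblasts and adipocytes. The series title poses the question of whether melatonin, a pineal hormone, acts on bone formation by senescent MSCs through chromatin remodelling by NSD2, an enzyme that methylates histone H3 at lysine 36. The age table held 3 young vehicle libraries (replicates 2, 4 and 5) and 3 old vehicle libraries (replicates 2, 8 and 9). The melatonin table held 3 other old vehicle libraries (replicates 1, 3 and 5) and 3 libraries labelled melatonin with the same replicate numbers. Library totals ran from 20595378 to 21309663 estimated counts, and 15591 to 16743 genes had a count. The labels do not say whether libraries came from separate animals, so p-values measure spread between these libraries. Within a group of 1 table, libraries correlated at r = 0.843 to 0.935, below the 0.977 to 0.996 of the 6 matched pairs described below. These values argue against library preparation alone as the source of that spread only if matched libraries share a culture. That was not established, and the pairs were picked by their r. Whether the spread lies between animals or between cultures was not tested.

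The comparison of old with young vehicle libraries asked how MSCs differ with donor age, with n = 3 libraries per group throughout. The macrophage gene Cd68 and the osteoblast genes Sp7, Alpl and Ibsp had higher mean levels in the old libraries, and the matrix genes Cthrc1 and Col3a1 had lower ones. Sp7 (gene identifier 170574), a transcription factor required for osteoblast formation, averaged 11.2 ± 6.32 CPM in old and 0.541 ± 0.243 CPM in young libraries, a log2 change of 4.35 ± 0.67 (SE). Cdkn1a (12575), which encodes the cell cycle inhibitor p21, averaged 585 ± 194 CPM in old and 240.1 ± 27.7 CPM in young libraries, a log2 change of 1.29 ± 0.29. Nsd2 (107823) averaged 69.5 ± 49.0 CPM in old and 82.6 ± 45.4 CPM in young libraries, a log2 change of -0.25 ± 0.60 (edgeR adjusted p = 0.874), which is smaller than the spread between libraries and ran from -0.996 to 0.30 as single libraries were left out. No single gene passed the adjusted threshold in this comparison, so the gene values here and below are given without a call.

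Macrophage genes rose as a list in old libraries (camera adjusted p = 3.29e-10, or adjusted p = 0.505 with an estimated correlation). All 20 measured members were higher, with a median log2 change of 5.14, and 20 passed when adjusted over the list alone. The lysosomal protein gene Cd68 (12514) averaged 654 ± 615 CPM in old and 18.1 ± 19.3 CPM in young libraries (log2 change 5.18 ± 1.44). Ptprc, which encodes the leukocyte antigen CD45, differed by 5.25 ± 1.47, the mannose receptor gene Mrc1 by 4.89 ± 1.40 and the CSF1 receptor gene Csf1r by 5.06 ± 1.48. The level was uneven within the old group, since the mean log2 CPM of the list was 9.17 in old vehicle replicate 8 and 9.01 in replicate 9, but 4.72 in replicate 2. It was 4.75, 1.07 and 2.12 in young replicates 2, 4 and 5. None of the 20 genes is in another list, and each had its 4 highest levels among all 12 libraries in old vehicle replicates 3, 5, 8 and 9. Lyz2, the lysozyme gene of myeloid cells, was at 5664 CPM or more in those 4 libraries and at 556 CPM or less in the other 8.

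Osteoblast genes differed in both directions, with 13 of 24 higher and 11 lower in old libraries, and the list did not pass (camera adjusted p = 0.282, or adjusted p = 0.683 with an estimated correlation). Sp7, Cthrc1, Bmp2 and Ibsp passed when adjusted over the list alone, with adjusted p = 0.0109 for both Sp7 and Cthrc1. Cthrc1 (68588), which encodes a secreted matrix protein, averaged 3.20 ± 1.63 CPM in old and 63.7 ± 43.6 CPM in young libraries (log2 change -4.31 ± 0.73). The bone morphogenetic protein gene Bmp2 differed by 2.66 ± 0.60. Ibsp, the bone sialoprotein gene, was at 65.3, 1.68 and 7.09 CPM in old replicates 2, 8 and 9, while its young mean of 0.107 CPM lay below the level of 3 counts. Alpl (11647), the alkaline phosphatase gene of mineralizing cells, averaged 62.2 ± 45.0 CPM in old and 1.43 ± 2.22 CPM in young libraries (log2 change 5.43 ± 1.67). Runx2 (12393), the earlier osteoblast regulator, had a log2 change of -0.44 ± 0.25, or 0.13 with the macrophage covariate, and the osteocalcin gene Bglap was below 1 CPM in every library of this table, with 0.46 ± 1.07. With the macrophage mean as a covariate the osteoblast list passed upward (camera adjusted p = 0.00391), as it did without old replicate 8 alone (adjusted p = 0.0190). Neither fit was repeated with an estimated correlation. Its direction was also upward without old vehicle replicates 8 and 9, those with the macrophage transcripts, which leaves a lone old library. The list averaged 4.66, 3.45 and 3.90 log2 CPM in old replicates 2, 8 and 9. In young replicates 2, 4 and 5 it averaged 3.75, 2.78 and 3.27.

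Genes of the senescence-associated secretory phenotype rose in old libraries, with 26 of 28 higher and a median log2 change of 1.22 (camera adjusted p = 1.00e-05, or adjusted p = 0.505 with an estimated correlation). Mmp13 (17386), a collagenase gene that mineralizing osteoblasts also express, averaged 108 ± 42.6 CPM in old and 2.65 ± 2.30 CPM in young libraries (log2 change 5.35 ± 0.84). The stromelysin gene Mmp3 differed by 3.29 ± 0.65, the chemokine gene Ccl7 by 2.68 ± 0.72 and the macrophage elastase gene Mmp12 by 6.26 ± 1.85. Mmp13 and Mmp3 were the 2 members that passed when adjusted over the list alone. The mean log2 CPM of the list was 5.03 and 4.99 in old replicates 8 and 9, which held the macrophage transcripts, against 3.41 in old replicate 2 and 3.58 in young replicate 2. Genes of senescence arrest rose as well, with 15 of 20 higher and a median of 0.28 (camera adjusted p = 0.0174, or adjusted p = 0.505 with an estimated correlation), and 2 of them, Bax and Cdkn1a, passed when adjusted over the list alone. Bax, a p53 target that promotes apoptosis, differed by 0.75 ± 0.17, the stress kinase gene Plk2 by -1.23 ± 0.41 and the stress cytokine gene Gdf15 by 4.0 ± 1.39. The arrest list averaged 6.34, 6.29 and 6.74 log2 CPM in old replicates 2, 8 and 9 and 6.49, 6.17 and 5.23 in young replicates 2, 4 and 5, so it did not follow the macrophage transcripts library by library. Its call was lost without old replicates 8 and 9 together (adjusted p = 0.0604) and without old replicate 2, old replicate 9 or young replicate 5 alone (adjusted p = 0.0847, 0.0731 and 0.295). Cdkn2a, which encodes the senescence marker p16, had a log2 change of -0.50 ± 1.38, or 1.24 by limma-voom, and ran from 1.31 to 245 CPM among young libraries. Trp53, the gene of p53, had -0.17 ± 0.21, and the lamin gene Lmnb1, whose loss marks senescence, had -0.96 ± 0.63. Proliferation genes fell, with 32 of 36 lower and a median of -0.61 (camera adjusted p = 0.00123, or adjusted p = 0.673 with an estimated correlation), and Mki67, the Ki-67 gene of cycling cells, had -0.69 ± 0.70. As single libraries were left out, Mki67 ran from -1.30 to -0.106 and Lmnb1 from -1.42 to -0.53. With the macrophage covariate Mki67 turned to 0.22. The proliferation call was lost without old replicate 9 or young replicate 4 (adjusted p = 0.878 and 0.649), and with the macrophage mean as a covariate the list passed in the other direction (adjusted p = 0.0192).

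Adipocyte genes rose in old libraries, with 10 of 15 higher and a median log2 change of 1.06 (camera adjusted p = 0.00315, or adjusted p = 0.505 with an estimated correlation). Pparg (19016), the main regulator of adipocyte formation, averaged 33.1 ± 7.05 CPM in old and 13.0 ± 3.35 CPM in young libraries (log2 change 1.35 ± 0.29). The adipogenic factor gene Cebpa differed by 2.73 ± 0.75, and the lipid uptake genes Lpl and Cd36 by 2.95 ± 0.91 and 6.64 ± 2.18. The last of these, Cd36, is also a macrophage gene, and it was at 563 and 224 CPM in old replicates 8 and 9 against 6.58 CPM in replicate 2. Cebpa had 744, 2365 and 6219 counts in old replicates 2, 8 and 9, and Lpl 1746, 3557 and 7082, so both were also higher in replicates 8 and 9. Pparg, with 772, 490 and 778 counts, did not follow them. With the macrophage mean as a covariate the adipocyte call was lost (camera adjusted p = 0.670). Antioxidant genes rose, with 20 of 22 higher and a median of 0.80 (camera adjusted p = 2.96e-06, or adjusted p = 0.505 with an estimated correlation). Of these, the peroxiredoxin gene Prdx6 differed by 1.77 ± 0.29 and alone passed when adjusted over the list alone, while the glutathione peroxidase gene Gpx1 differed by 0.73 ± 0.19, G6pdx, which supplies NADPH, by 1.07 ± 0.28 and the catalase gene Cat by 1.45 ± 0.43. The antioxidant list averaged 6.53, 6.81 and 7.31 log2 CPM in old replicates 2, 8 and 9, with the 2 higher values in the libraries with macrophage transcripts. Contractile genes of smooth muscle rose too, with 13 of 16 higher and a median of 0.72 (camera adjusted p = 0.00123, or adjusted p = 0.505 with an estimated correlation). The myosin kinase gene Mylk was at 54.5, 200.2 and 226 CPM in old replicates 2, 8 and 9 and had a log2 change of 2.81 ± 0.54, while Tpm2, Des and Myl9 differed by 0.63 ± 0.25, 3.19 ± 1.33 and 0.50 ± 0.22. The value of Des rests mainly on old replicate 9, at 34.5 CPM against 1.37 and 6.94 CPM in replicates 2 and 8, and it turned to -0.61 with the macrophage covariate and -0.19 without replicates 8 and 9.

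Collagen matrix genes fell in old libraries, with 21 of 25 lower and a median log2 change of -0.88 (camera adjusted p = 0.00123, or adjusted p = 0.505 with an estimated correlation). The crosslinking enzyme gene Loxl2 went the other way, averaging 242 ± 70.0 CPM in old and 12.6 ± 9.32 CPM in young libraries (log2 change 4.26 ± 0.79), and alone passed when adjusted over the list alone. The related gene Loxl1 differed by -1.19 ± 0.29, Col3a1 of collagen III by -2.74 ± 0.92 and the elastin gene Eln by -4.57 ± 1.62. Col3a1 had 149906 counts in young replicate 5 against 28114 and 15248 in young replicates 2 and 4. Its change ran from -3.21 to -1.07 as single libraries were left out. Eln had 3 counts in young replicate 4, fewer than the 12 in old replicates 2 and 9. Cholesterol synthesis genes fell, with 20 of 21 lower and a median of -0.56 (camera adjusted p = 1.28e-04, or adjusted p = 0.505 with an estimated correlation). Their regulator gene Srebf2 differed by -0.76 ± 0.17, and the synthesis enzyme gene Hmgcs1 by -0.77 ± 0.36. The collagen list averaged 8.71, 7.42 and 7.55 log2 CPM in old replicates 2, 8 and 9, and the cholesterol list 5.62, 4.58 and 4.72, so among these 3 both were lower in the libraries with high macrophage transcripts. In young replicates 2, 4 and 5 the collagen list averaged 8.66, 7.66 and 9.44 and the cholesterol list 5.57, 5.98 and 5.05, so the collagen list was also low in young replicate 4, where macrophage transcripts were lowest. Without replicates 8 and 9 both calls were lost, with adjusted p = 0.954 for each, and the collagen call was also lost without young replicate 5 (adjusted p = 0.0697). Chromatin genes that include the H3 lysine 36 methyltransferases fell, with 19 of 22 lower and a median of -0.28 (camera adjusted p = 0.00167, or adjusted p = 0.505 with an estimated correlation). The methyltransferase genes Setd2, Ash1l and Nsd1 differed by -0.64 ± 0.19, -0.58 ± 0.22 and -0.35 ± 0.16, and the chromatin protein gene Hmgb2 by -1.10 ± 0.43. Their list mean was 5.49, 5.68 and 5.09 log2 CPM in old replicates 2, 8 and 9, and 5.53, 5.97 and 5.78 in young replicates 2, 4 and 5. The list also holds chromatin genes of other roles, such as Hmgb2, so its fall is not that of the methyltransferases alone. With the macrophage mean as a covariate the chromatin call was lost (camera adjusted p = 0.460).

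The other lists that passed camera with the preset correlation were antigen presentation (15 of 16 higher, median log2 change 2.06, adjusted p = 7.06e-05), NF-kB inflammation (18 of 19 higher, 1.27, adjusted p = 4.29e-04) and BMP and TGF-beta targets (15 of 17 higher, 0.39, adjusted p = 0.0184). Ribosomal protein genes fell, with 26 of 26 lower and a median of -0.39 (adjusted p = 0.00120, or adjusted p = 0.635 with an estimated correlation). For the first 3 the value was adjusted p = 0.505 with an estimated correlation. Without young replicate 5 the ribosomal and the BMP and TGF-beta calls were lost (adjusted p = 0.906 and 0.143), and without old replicate 9 the latter was (adjusted p = 0.0613). Antigen presentation genes averaged 2.83, 5.96 and 4.95 log2 CPM in old replicates 2, 8 and 9, and NF-kB genes 2.79, 4.84 and 5.13, which are higher where macrophage transcripts were. In all, 14 of 26 lists passed, 9 upward and 5 downward, and 0 passed with an estimated correlation or with fry. With the macrophage mean as a covariate, 0 of these 14 passed in the same direction. That covariate is the mean of the macrophage list, so the loss of this list was fixed in advance. It also differed between the groups, so it can take up changes that go with age. Without old replicates 8 and 9, which leaves a lone old library, 2 of the 14 turned direction. The macrophage list still pointed upward there, with 4.72 log2 CPM in old replicate 2 against 4.75, 1.07 and 2.12 in the young libraries. With the covariate, antigen presentation and NF-kB genes passed downward (adjusted p = 0.0192 and 0.00391), and without the 2 libraries both calls were lost (adjusted p = 0.861 for each). Interferon genes, with 19 of 25 higher, did not pass (camera adjusted p = 0.149, or 0.752 with an estimated correlation). They passed upward without old replicate 2 or young replicate 2 (adjusted p = 2.88e-07 and 0.0103) and downward with the covariate (adjusted p = 1.02e-37). The last value rests on the preset correlation, which treats the genes as nearly independent. Without old replicates 8 and 9 the direction was also downward. Their list averaged 2.94, 5.74 and 5.62 log2 CPM in old replicates 2, 8 and 9. In young replicates 2, 4 and 5 it averaged 4.90, 3.44 and 3.83.

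Among all genes, those with the smallest p-values that were higher in old libraries included Efnb1, a ligand of Eph receptors (log2 change 1.998 ± 0.27), Emp3 (1.07 ± 0.16) and the AMP deaminase Ampd3 (2.12 ± 0.33). Lower ones were the serine synthesis enzyme Phgdh (-1.19 ± 0.18), the transcription factor Tcf4 (-1.50 ± 0.23), Pear1 (-2.74 ± 0.44) and the guidance factor Slit2 (-1.49 ± 0.26). Mmp13 and Cthrc1, given above, were also among them. For Tcf4 the levels were 103 ± 24.9 CPM in old and 291 ± 15.5 CPM in young libraries. The edgeR test called 0 of 13547 genes, with 1865 at an unadjusted p under 0.05 (13.8%), a smallest adjusted p of 0.315 and a biological coefficient of variation of 0.481. DESeq2 called 868 genes, 664 higher and 204 lower, with 2300 unadjusted, and limma-voom called 0, with 1391 unadjusted. The groups did not overlap for 18.5% of genes, where chance gives 10% on average over splits. Genes do not vary independently, so a single split can lie far from that average.

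**Figure D1:**
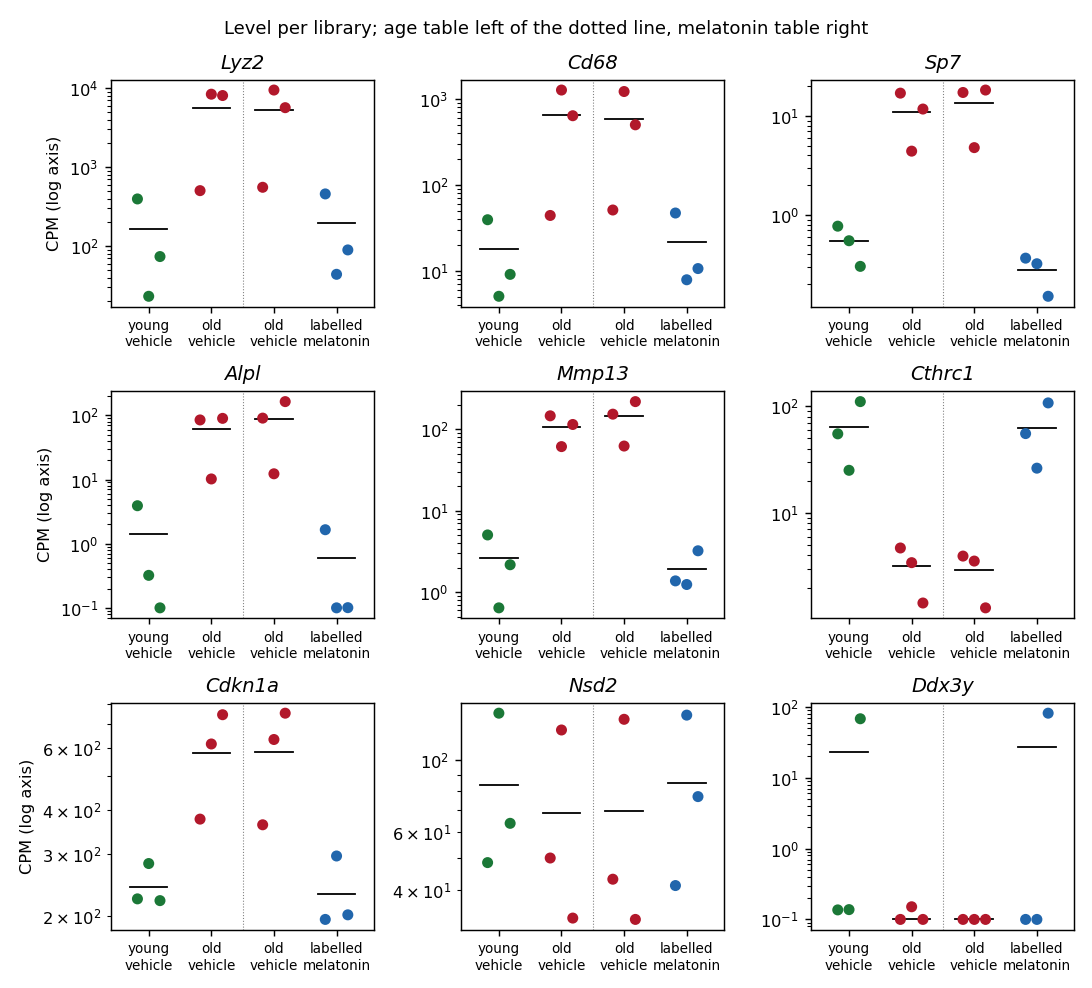
Level of 9 genes in each library, in CPM on a log axis, with 1 point per library, black bars for group means and values under 0.1 CPM drawn at 0.1. Lyz2 was at 5664 CPM or more in 4 old vehicle libraries, and Ddx3y was high in 1 young library and 1 library labelled melatonin.

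**Figure D2:**
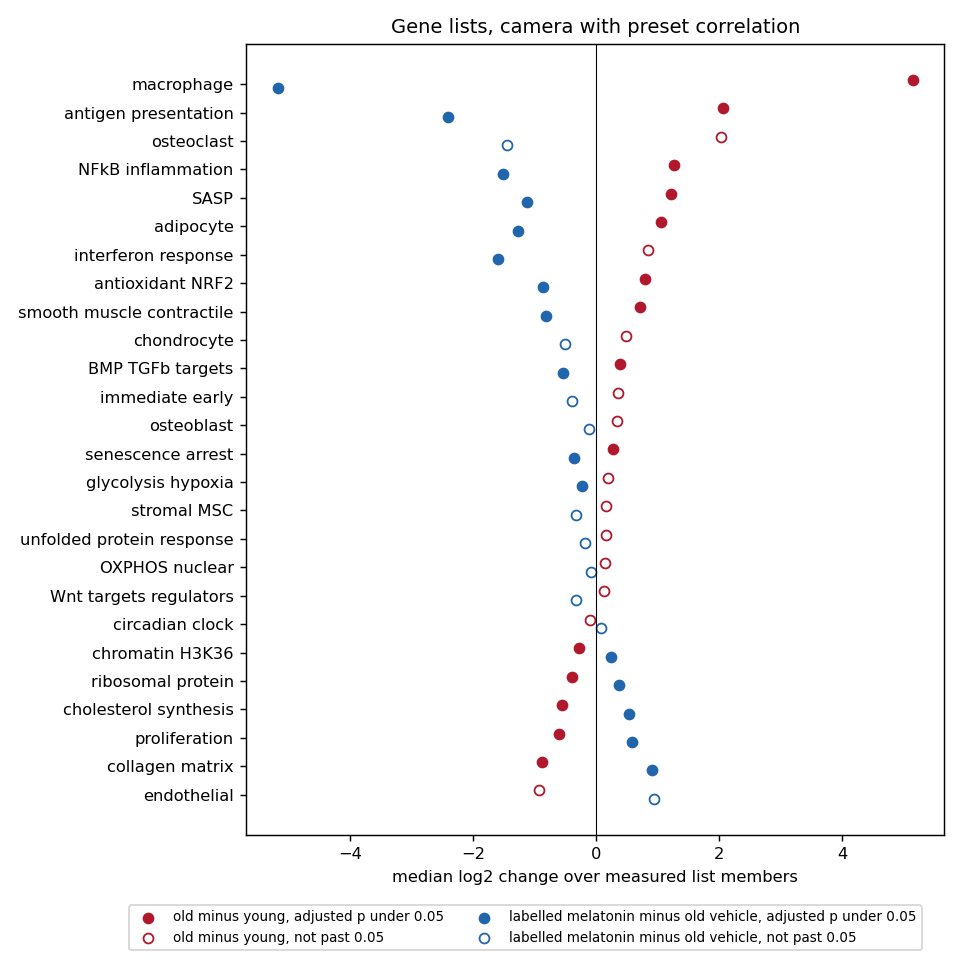
Median log2 change over the measured members of each tested list, old minus young in red and labelled melatonin minus old vehicle in blue, with filled points at a camera adjusted p under 0.05. The macrophage list lay farthest from 0, at 5.14 and -5.17.

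Each library of one table had a single close counterpart in the other, across the labelled groups. The old vehicle libraries paired as replicates 1 and 2 (Pearson r = 0.996 across 12691 genes), 3 and 8 (0.994), and 5 and 9 (0.977). The library labelled melatonin replicate 1 paired with young replicate 2 (0.991), replicate 3 with young replicate 4 (0.995) and replicate 5 with young replicate 5 (0.994). The highest r of any other pair was 0.952, and young libraries correlated with each other at 0.875 to 0.917. These r are across genes, which are not independent replicates, and in all 6 pairs each library was the other's highest r. Libraries labelled melatonin correlated with the old vehicle library of the same number at 0.945, 0.775 and 0.713 for replicates 1, 3 and 5. Within the 3 pairs of libraries labelled melatonin and young, edgeR called 6 of 13344 genes, 3 higher and 3 lower, with 433 at an unadjusted p under 0.05 and a smallest adjusted p of 0.00940. Within the 3 old vehicle pairs it called 0, with 525 unadjusted, and across all 6 pairs 0, with 648 unadjusted, and no other tool was run on the pairs. Single genes marked the pairs. Agtr2, an angiotensin receptor gene, was at 535 CPM in the library labelled melatonin replicate 5 and at 465 CPM in young replicate 5, and at 1.28 CPM or less elsewhere. Marco, a scavenger receptor gene of macrophages, was at 622 and 362 CPM in old vehicle replicates 5 and 9 and at 16.8 CPM or less elsewhere. The potassium channel gene Kcne4 was at 52.6 CPM in the library labelled melatonin replicate 1 and 47.3 CPM in young replicate 2. Y-linked genes set apart the pair of the library labelled melatonin replicate 5 and young replicate 5, and do not bear on the other pairs. Ddx3y was at 81.7 CPM in the library labelled melatonin replicate 5 and at 68.1 CPM in young replicate 5, with 0 counts in old vehicle replicate 5, which allows up to 3 counts, and 0.151 CPM or less in every other library. Eif2s3y was at 65.0 and 66.1 CPM in the same 2 libraries and at 0.363 CPM or less elsewhere. Uty was less clearly apart, at 39.8 and 36.3 CPM in these libraries and at up to 9.95 CPM elsewhere. Kdm5d was low throughout, at 0.403 and 0.404 CPM against up to 0.227 CPM elsewhere. In the age table, young replicate 5 was thus alone in high Ddx3y and Eif2s3y. Whether the age calls lost without that library relate to this difference was not tested.

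**Figure D3:**
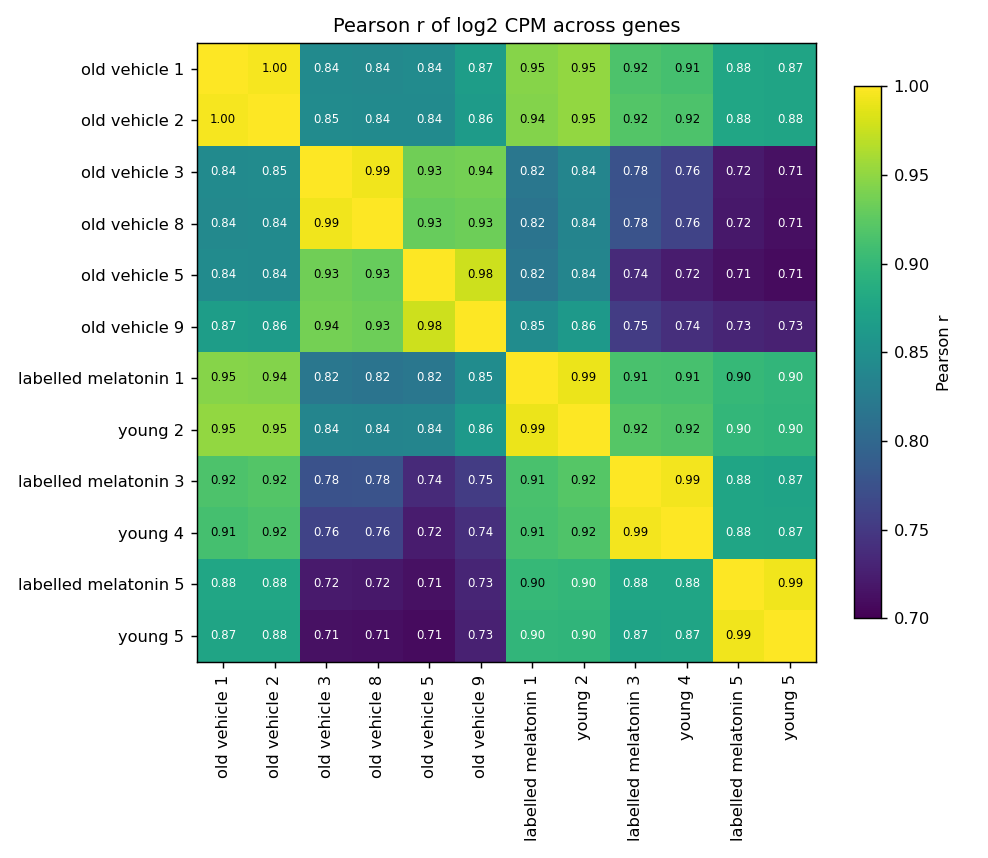
Pearson r of log2 CPM across 12691 genes for each pair of the 12 libraries, ordered so that matched libraries of the 2 tables lie side by side. The 6 matched pairs had r of 0.977 to 0.996, and the highest other pair had 0.952.

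The comparison of libraries labelled melatonin with old vehicle libraries asked what 1 µM melatonin for 24 h does to old MSCs, with n = 3 libraries per group. Its directions rest on the labels, although each library labelled melatonin was closest to a young vehicle library. Mean levels of the macrophage gene Csf1r and the osteoblast genes Sp7, Alpl and Ibsp were lower in libraries labelled melatonin, and those of the matrix genes Cthrc1 and Col3a1 were higher. Sp7 averaged 0.277 ± 0.114 CPM in libraries labelled melatonin and 13.6 ± 7.66 CPM in old vehicle, a log2 change of -5.59 ± 0.72. Cdkn1a averaged 227 ± 47.9 and 590.4 ± 209 CPM, a log2 change of -1.38 ± 0.34. Nsd2 averaged 83.2 ± 44.9 and 70.1 ± 55.7 CPM, a log2 change of 0.25 ± 0.65 (edgeR adjusted p = 0.877), smaller than the spread between libraries and from -0.25 to 1.16 as single libraries were left out. On the scale of all 12 libraries, Nsd2 was at 41.2, 137 and 77.1 CPM in the libraries labelled melatonin replicates 1, 3 and 5, and at 43.1, 133 and 32.4 CPM in the old vehicle libraries of the same numbers.

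Macrophage genes fell as a list in libraries labelled melatonin, with 19 of 19 lower and a median log2 change of -5.17 (camera adjusted p = 2.41e-10, or adjusted p = 0.543 with an estimated correlation), and 19 passed when adjusted over the list alone. The integrin gene Itgam differed by -6.46 ± 1.58, Csf1r by -5.18 ± 1.27, Adgre1, which encodes the F4/80 antigen, by -6.19 ± 1.65 and the complement gene C1qb by -5.25 ± 1.42. The mean log2 CPM of the list was 9.27 and 9.001 in old vehicle replicates 3 and 5 but 4.81 in replicate 1. It was 4.58, 1.89 and 2.51 in the libraries labelled melatonin replicates 1, 3 and 5.

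Osteoblast genes again went both ways, with 12 of 24 higher and 12 lower, and the list did not pass (camera adjusted p = 0.271, or adjusted p = 0.613 with an estimated correlation). Sp7, Cthrc1, Alpl and Ibsp passed when adjusted over the list alone. Cthrc1 averaged 62.8 ± 41.3 CPM in libraries labelled melatonin and 2.94 ± 1.41 CPM in old vehicle (log2 change 4.41 ± 0.71), and Alpl averaged 0.607 ± 0.927 and 90.3 ± 77.9 CPM (-7.20 ± 1.61). Ibsp had 0, 0 and 1 counts in the libraries labelled melatonin and 68.0, 1.94 and 2.89 CPM in old vehicle replicates 1, 3 and 5. Runx2 had a log2 change of 0.28 ± 0.26, or -0.18 with the macrophage covariate, and Bglap, with 0.17 ± 1.02, was again below 1 CPM in every library of the table. With the macrophage mean as a covariate the osteoblast list passed downward (camera adjusted p = 3.34e-04), as it did without old vehicle replicate 3 alone (adjusted p = 0.0167). Neither fit was repeated with an estimated correlation. Its direction was also downward without old vehicle replicates 3 and 5, those with the macrophage transcripts, which leaves a lone old vehicle library. The list averaged 4.75, 3.43 and 3.98 log2 CPM in old vehicle replicates 1, 3 and 5. In the libraries labelled melatonin it averaged 3.64, 2.79 and 3.30.

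Secretory phenotype genes fell in libraries labelled melatonin, with 24 of 26 lower and a median log2 change of -1.12 (camera adjusted p = 1.48e-04, or adjusted p = 0.543 with an estimated correlation). Mmp13 averaged 1.93 ± 1.11 CPM in libraries labelled melatonin and 147 ± 80.9 CPM in old vehicle (log2 change -6.25 ± 0.70) and alone passed when adjusted over the list alone (adjusted p = 0.00259). Mmp3 differed by -4.12 ± 0.92, and the cytokine genes Tnf and Ccl2 by -6.34 ± 1.66 and -3.14 ± 0.89. With the macrophage covariate Tnf turned to 1.23. The list averaged 4.81 and 5.12 log2 CPM in old vehicle replicates 3 and 5, which held the macrophage transcripts, against 3.24 in replicate 1 and 3.20 in the library labelled melatonin replicate 1. Senescence arrest genes fell, with 13 of 20 lower and a median of -0.36 (camera adjusted p = 0.00922, or adjusted p = 0.543 with an estimated correlation), and 0 of them passed edgeR when adjusted over the list alone, with 2 higher and 6 lower at an unadjusted p under 0.05. Bax differed by -0.76 ± 0.20, the p53 target gene Zmat3 by -0.66 ± 0.20 and Gdf15 by -4.25 ± 1.31. Their list averaged 6.35, 6.29 and 6.54 log2 CPM in old vehicle replicates 1, 3 and 5 and 6.39, 6.21 and 5.15 in the libraries labelled melatonin, so the library labelled melatonin replicate 5 was the lowest. Without that library or old vehicle replicate 1 the arrest call was lost (adjusted p = 0.219 and 0.0642). Cdkn2a had a log2 change of 0.85 ± 1.39, or -0.86 by limma-voom, Trp53 0.05 ± 0.23 and Lmnb1 1.00 ± 0.56. Proliferation genes rose, with 33 of 36 higher and a median of 0.58 (camera adjusted p = 0.00224, or adjusted p = 0.605 with an estimated correlation), and Mki67 had 0.76 ± 0.63. That call was lost without the library labelled melatonin replicate 3 or old vehicle replicate 5 (adjusted p = 0.965 and 0.370), and with the macrophage mean as a covariate the list passed in the other direction (adjusted p = 0.0263). As single libraries were left out, Mki67 ran from 0.312 to 1.28 and Lmnb1 from 0.595 to 1.33. With that covariate they turned to -0.016 and -0.013.

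Adipocyte genes fell in libraries labelled melatonin, with 11 of 15 lower and a median log2 change of -1.27 (camera adjusted p = 0.00255, or adjusted p = 0.543 with an estimated correlation), and 4 passed when adjusted over the list alone. Pparg averaged 13.3 ± 2.49 CPM in libraries labelled melatonin and 41.1 ± 19.0 CPM in old vehicle (log2 change -1.63 ± 0.38), Cebpa differed by -3.23 ± 0.78 and Cd36 by -7.58 ± 1.81. The adiponectin gene Adipoq averaged 3.19 ± 2.46 CPM in old vehicle and lay at or below the level of 3 counts in the libraries labelled melatonin. Antioxidant genes fell, with 18 of 22 lower and a median of -0.86 (camera adjusted p = 2.49e-05, or adjusted p = 0.543 with an estimated correlation). Of these, Prdx6 differed by -1.40 ± 0.23, G6pdx by -1.07 ± 0.28, Cat by -1.53 ± 0.41 and the plasma peroxidase gene Gpx3 by -4.90 ± 1.30, and all 4 passed when adjusted over the list alone. Contractile genes fell, with 15 of 16 lower and a median of -0.82 (camera adjusted p = 1.32e-04, or adjusted p = 0.543 with an estimated correlation). Mylk differed by -3.35 ± 0.76, Tagln by -0.89 ± 0.24, the actin gene Acta2 by -0.94 ± 0.29 and Tpm2 by -0.65 ± 0.20. In old vehicle replicates 1, 3 and 5 the adipocyte list averaged 2.37, 2.84 and 3.90 log2 CPM, the antioxidant list 6.46, 6.79 and 7.27 and the contractile list 7.49, 8.09 and 8.13, each higher in the libraries with macrophage transcripts.

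Collagen matrix genes rose in libraries labelled melatonin, with 22 of 25 higher and a median log2 change of 0.91 (camera adjusted p = 0.00248, or adjusted p = 0.602 with an estimated correlation). Loxl2 again went the other way, at 10.3 ± 7.04 CPM in libraries labelled melatonin and 267 ± 21.9 CPM in old vehicle (log2 change -4.70 ± 0.75), and alone passed when adjusted over the list alone. Loxl1 differed by 0.95 ± 0.24, Eln by 5.07 ± 1.78 and Col3a1 by 2.41 ± 0.94. Col3a1 had 154071 counts in the library labelled melatonin replicate 5 against 27204 and 14904 in replicates 1 and 3. Its change ran from 0.70 to 2.89 as single libraries were left out. Eln had 1 count in the library labelled melatonin replicate 3, fewer than the 14 in old vehicle replicate 1. Cholesterol synthesis genes rose, with 20 of 21 higher and a median of 0.54 (camera adjusted p = 4.72e-04, or adjusted p = 0.602 with an estimated correlation). Srebf2 differed by 0.64 ± 0.19, Hmgcs1 by 0.79 ± 0.35, Cyp51 by 0.94 ± 0.51 and Fdps by 0.73 ± 0.45. As single libraries were left out, Cyp51 ran from 0.435 to 1.46 and Fdps from 0.243 to 1.12. With the macrophage covariate Hmgcs1, Cyp51 and Fdps turned to -0.16, -0.22 and -0.30. The collagen list averaged 8.80, 7.56 and 7.51 log2 CPM in old vehicle replicates 1, 3 and 5, and the cholesterol list 5.55, 4.62 and 4.53, both lower in replicates 3 and 5, which had the macrophage transcripts. In the libraries labelled melatonin replicates 1, 3 and 5 the collagen list averaged 8.81, 7.596 and 9.52 and the cholesterol list 5.42, 6.05 and 4.96, so the collagen list was also low in replicate 3, without high macrophage transcripts. Without replicates 3 and 5 both calls were lost, with adjusted p = 0.804 and 0.905. Without the library labelled melatonin replicate 5 the collagen call was lost (adjusted p = 0.210), and without replicate 3 the cholesterol call was (adjusted p = 0.121). With the macrophage mean as a covariate the cholesterol list passed downward (adjusted p = 0.0491). Chromatin genes rose, with 17 of 22 higher and a median of 0.24 (camera adjusted p = 0.00384, or adjusted p = 0.543 with an estimated correlation). The methyltransferase genes Setd2 and Ash1l differed by 0.63 ± 0.17 and 0.57 ± 0.17, Hmgb2 by 1.15 ± 0.40 and the heterochromatin protein gene Cbx5 by 0.68 ± 0.31. Their list mean was 5.49, 5.72 and 5.23 log2 CPM in old vehicle replicates 1, 3 and 5, and 5.53, 5.97 and 5.88 in the libraries labelled melatonin. The chromatin call was lost with the macrophage covariate (camera adjusted p = 0.245).

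Lower as lists in libraries labelled melatonin were also antigen presentation (16 of 16 lower, median log2 change -2.40, adjusted p = 4.39e-05, or adjusted p = 0.585 with an estimated correlation) and NF-kB inflammation (17 of 18, -1.51, adjusted p = 4.09e-04, or adjusted p = 0.595 with an estimated correlation). Interferon response genes fell (24 of 25 lower, -1.59, adjusted p = 0.00421, or adjusted p = 0.605 with an estimated correlation). Without old vehicle replicates 3 and 5, which leaves a lone old vehicle library, the direction of this list turned upward. BMP and TGF-beta targets (12 of 17 lower, -0.54, adjusted p = 0.0163, or adjusted p = 0.543 with an estimated correlation) and glycolysis and hypoxia genes (19 of 24 lower, -0.23, adjusted p = 0.0202, or adjusted p = 0.564 with an estimated correlation) fell as well. Ribosomal protein genes rose, with 26 of 26 higher and a median of 0.37 (adjusted p = 6.03e-04, or adjusted p = 0.605 with an estimated correlation). Leaving out single libraries ended calls on 4 of these lists. Without the library labelled melatonin replicate 5 they were ribosomal, BMP and TGF-beta, and glycolysis and hypoxia genes (adjusted p = 0.621, 0.0837 and 0.141), and without replicate 3 the interferon and glycolysis lists (0.0771 and 0.0828). Without old vehicle replicate 1 the BMP and TGF-beta and the glycolysis lists both had an adjusted p of 0.0602, without replicate 3 the glycolysis list had 0.189, and without replicate 5 the interferon list had 0.292. The antigen presentation list averaged 2.80, 5.93 and 5.37 log2 CPM in old vehicle replicates 1, 3 and 5, the NF-kB list 2.88, 4.62 and 5.63 and the interferon list 2.95, 5.77 and 6.51, each higher in replicates 3 and 5, as macrophage transcripts were. In all, 16 of 26 lists passed, 5 upward and 11 downward, and 0 passed with an estimated correlation or with fry. With the macrophage mean as a covariate, 0 of these 16 passed in the same direction. The loss of the macrophage list was fixed in advance, as its mean is the covariate, which also differed between the groups. Without old vehicle replicates 3 and 5, which leaves a lone old vehicle library, 3 of the 16 turned direction. The macrophage list still pointed downward there, with 4.81 log2 CPM in old vehicle replicate 1 against 4.58, 1.89 and 2.51 in the libraries labelled melatonin. With the covariate, antigen presentation and interferon genes passed upward (camera adjusted p = 0.0318 and 1.19e-21). Both values rest on the preset correlation, which treats the genes of a list as nearly independent. Without the 2 libraries the antigen presentation, NF-kB and glycolysis calls were lost (adjusted p = 0.740, 0.471 and 0.620).

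The smallest p-values of genes higher in libraries labelled melatonin were those of the chromatin reader Psip1 (log2 change 1.25 ± 0.20), Pear1 (2.67 ± 0.42), Cthrc1, Tcf4 (1.51 ± 0.25) and Tanc1 (0.89 ± 0.17). Lower ones included Mmp13, Efnb1 (-2.30 ± 0.28), Glipr1 (-4.75 ± 0.65) and Rassf3 (-2.12 ± 0.31). Psip1 was at 98.0 ± 8.80 CPM in libraries labelled melatonin and 41.1 ± 8.10 CPM in old vehicle. The edgeR test called 0 of 13471 genes, with 1914 at an unadjusted p under 0.05 (14.2%), a smallest adjusted p of 0.286 and a biological coefficient of variation of 0.482. DESeq2 called 895 genes, 187 higher and 708 lower, with 2368 unadjusted, and limma-voom called 0, with 1403 unadjusted. Without old vehicle replicate 1, edgeR called 602 genes, 69 higher and 533 lower. The groups did not overlap for 18.9% of genes, where chance gives 10% on average over splits, with the limit given for the age comparison.

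The age and melatonin changes opposed each other across genes. Over 13355 genes tested in both tables the log2 changes correlated at Pearson r = -0.973 and Spearman rho = -0.940, with a covariance of -1.35, and 90.7% of genes had opposite signs. Of 1485 genes with an unadjusted p under 0.05 in both tables, 1485 had opposite signs. Mmp13, Sp7 and Loxl2 lay at one end, higher in old and lower in libraries labelled melatonin, and Cthrc1 and Pear1 at the other. By label the 2 comparisons share no library, but each library of one table matched a library of the other. Splitting the matched libraries in the same other ways in both tables gave r of 0.872 to 0.970 in size, and genes are not independent replicates.

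**Figure D4:**
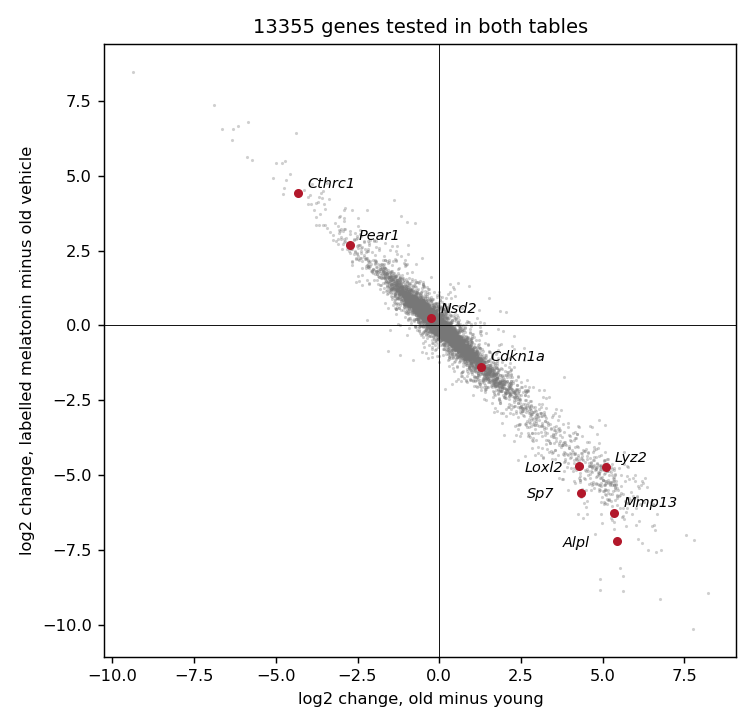
Log2 change of 13355 genes, old minus young on the horizontal axis and labelled melatonin minus old vehicle on the vertical axis, with 1 point per gene and named genes in red. The points follow a falling line (r = -0.973), with Nsd2 near the origin at -0.25 and 0.25.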

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

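The test for a library apart from the others covered several named genes that were chosen for the text only after the result was seen. Among the 6 old vehicle libraries of both tables, 3 genes had replicate 5 below all others by more than Dixon's 95% critical value for 6 samples, taken as the gap to the next library over the whole range of log2 CPM. Phgdh, the serine synthesis enzyme gene, was at 46.8 CPM in replicate 5 and at 90.4 to 115 CPM in the other libraries, a ratio of 0.732. Chac1, an amino acid response gene, was at 4.01 CPM in replicate 5 and at 7.82 to 10.3 CPM in the others, a ratio of 0.709. Cspg4, a pericyte proteoglycan gene, was at 6.26 CPM in replicate 5 and at 20.1 to 35.7 CPM in the others, a ratio of 0.668. Of 110 items tested, 3 lay past this value, where chance gives about 1 in 20 for independent samples. These 6 libraries are not independent, since they match in 3 close pairs across the tables, so neither the critical value nor this share holds for them as it stands.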

How the results depend on the processing

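Limma-voom, the macrophage covariate, the removal of the 2 libraries richest in macrophage transcripts, and leaving out libraries for lists and for agreement were chosen only after the result was seen. For counts of genes the edgeR value of 0 held in both comparisons with DESeq2 size factors, without the filter, at an adjusted p under 0.1 and with limma-voom. The unadjusted counts for age and melatonin were 1865 and 1914, or 1865 and 1913 with DESeq2 size factors, 2213 and 2286 without the filter, and 1391 and 1403 by limma-voom. The DESeq2 Wald test gave 868 genes for age and 895 for melatonin, and all old vehicle libraries against young gave 46 (17 higher, 29 lower), which counts near-duplicate libraries as separate; the cause was not tested. Leaving out single libraries gave 0 to 0 genes for age and 0 to 602 for melatonin, with 602 without old vehicle replicate 1 and 0 without any other. The number of lists was 0 and 0 with an estimated correlation, 7 and 7 with the macrophage covariate (3 up and 4 down each), 10 to 16 for age and 11 to 16 for melatonin without single libraries, and 10 and 13 without the 2 richest libraries, where the lone remaining old library is assumed to vary like the other group. Gene counts stayed at 0 with the covariate (285 and 254 unadjusted) and without those 2 libraries (268 and 286 unadjusted), which leaves fewer samples. The agreement of both changes ran from -0.961 to -0.914 without single libraries and was -0.985 over genes above the median level. Deviations of libraries with the same number in the labels correlated at -0.274, 0.1005 and -0.0295, and those with unlike numbers at -0.257 to 0.337. With so few libraries these values show no pairing by number, but cannot decide whether same-number libraries share a donor. As a block the number gave 0 genes (1124 unadjusted) and 16 lists.

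Log2 changes of named genes turned under some settings, and the cause was not tested. With the macrophage covariate the age values were Runx2 0.13, Bglap -0.33, Trp53 0.0067, Mki67 0.22, Cd36 -0.044, Hmgcs1 0.12, Gdf15 -0.16 and Des -0.61. The melatonin values were Runx2 -0.18, Bglap -0.62, Trp53 -0.14, Mki67 -0.016, Lmnb1 -0.013, Hmgcs1 -0.16, Cyp51 -0.22, Fdps -0.30, Cbx5 -0.056, Itgam 0.27, Adgre1 0.027, Tnf 1.23 and Gdf15 0.095. Itgam and Adgre1 are members of the list that forms the covariate, so the loss of their change was built in. Without the 2 richest libraries Runx2 had 0.033 and Des -0.19 for age, and Runx2 -0.097 and Bglap -0.84 for melatonin. Limma-voom gave Cdkn2a 1.24 for age, and Cdkn2a -0.86 and Bglap -0.075 for melatonin, and the block gave Cdkn2a -0.20. Without single libraries Nsd2 ran from -0.996 to 0.30, Bglap from -0.13 to 1.26 and Cdkn2a from -1.08 to 1.24 for age. For melatonin Nsd2 ran from -0.25 to 1.16, Bglap from -0.40 to 1.22, Cdkn2a from -0.88 to 1.45 and Trp53 from -0.17 to 0.24. The pseudocount alternatives were not run, since normalized values were not tested, and agreement over genes changed with age gave no value, since no gene passed.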

Other observations

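The tests of the library match and of macrophage transcripts, and the counts over splits other than those for gene lists, were chosen only after the result was seen.

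Genes of the unfolded protein response did not move as a list, with a camera adjusted p of 0.218 for age and 0.298 for melatonin. The asparagine synthetase gene Asns averaged 84.8 ± 11.4 CPM in old and 154 ± 42.4 CPM in young libraries (n = 3 each, log2 change -0.86 ± 0.25), and Chac1, which degrades glutathione, differed by -1.59 ± 0.50. Sdf2l1 and Dnajb9 of the endoplasmic reticulum differed by 1.41 ± 0.43 and 0.52 ± 0.18. In libraries labelled melatonin against old vehicle, Asns, Chac1 and the stress factor gene Ddit3 differed by 1.02 ± 0.32, 1.71 ± 0.53 and 1.28 ± 0.39, and Sdf2l1 by -1.43 ± 0.42. None of these genes passed the adjusted threshold.

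Stromal marker genes of marrow MSCs also did not move as a list (camera adjusted p = 0.685 for age and 0.520 for melatonin). The leptin receptor gene Lepr, which marks perivascular marrow stroma, was at 25.7 CPM in old vehicle replicate 2, 0.765 CPM in replicate 8 and 1.46 CPM in replicate 9, against a mean of 0.299 ± 0.0616 CPM in young libraries. The adhesion gene Vcam1 differed by 1.61 ± 0.55 with age and -1.68 ± 0.53 in libraries labelled melatonin, the stem cell factor gene Kitl by 0.85 ± 0.37 and -0.91 ± 0.39, and the pericyte proteoglycan gene Cspg4 by -1.94 ± 0.54 and 2.15 ± 0.79. As single libraries were left out, Kitl ran from 0.457 to 1.13 with age and from -1.12 to -0.405 in libraries labelled melatonin. None of the 4 passed the adjusted threshold.

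Libraries of the 2 tables matched one to one, with old vehicle libraries matched to old vehicle and libraries labelled melatonin to young vehicle. The same library deposited under 2 names is argued against by the lowest median chi-square ratio of a matched pair, which was 1.74 times that of counting error. Melatonin moving cells to the young state is argued against for replicates 1 and 3 by the lower r with a young library, which was 0.991, above 0.917, the highest between young libraries. For replicate 5 that r was 0.994. The Y-linked gene Ddx3y was at 81.7 CPM in replicate 5, with 0 counts in the old vehicle library of that number. This difference argues against it only if libraries of the same number share a donor, which was not established. The same 6 cultures in both tables under other names is a candidate explanation, since the lowest r of a matched pair was 0.977 and the highest r of any other pair 0.952, and it would make the opposite changes of the 2 comparisons 1 difference measured again. Within the pairs of libraries labelled melatonin and young, edgeR called 6 genes (433 unadjusted), and within the old vehicle pairs 0 (525 unadjusted), and the cause of the 6 is open.

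Macrophage transcripts were high in old vehicle replicates 3, 5, 8 and 9, which by the match could be 2 cultures. Macrophages in these cultures are a candidate explanation, since 20 of 20 list genes had their 4 highest levels there, with Lyz2 at 5664 CPM or more and C1qa at 1180.5 CPM or more, and the labels name no sort that would remove them. Carry-over of unsorted marrow blood cells as the whole source was examined by S100a8, S100a9, Ngp, Hba-a1 and Hbb-bt, abundant granulocyte and erythroid transcripts. They reached 4.30 CPM at most there, below 17.1 CPM, the lowest level of any macrophage list gene. This argues against carried-over blood cells with granulocytes and erythroid cells still among them. It cannot decide on marrow macrophages that stayed in culture while those other cells were lost. A smaller granulocyte share stays open, since Csf3r reached 26.4 CPM and Mmp8 17.0 CPM there against 1.64 and 1.18 CPM at most elsewhere; its list had 4 and 3 measured genes, too few to test, and of 8 fits without a single library that measured enough, it passed only in the 2 without old replicate 2 or old vehicle replicate 1, which have the lowest macrophage mean of the old libraries in their table (adjusted p from 0.00541 to 0.541 over the 8). Donor age stays open and untested as a cause, because 2 of 3 old vehicle libraries of the age table lay above every young library while replicate 2 lay at 4.72, against 4.75 in young replicate 2.

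The 10 splits of 6 libraries are too few for a share under 0.05. For the edgeR count of genes the real value was 0 and the highest other split gave 0 in both comparisons, so 10 of 10 splits gave as many. For genes at an unadjusted p under 0.05 the real count was 1865 with age and the highest other was 1456, and it was 1914 for melatonin with 1494 as the highest other, so 1 split of 10 reached each real count. For gene lists the real count was 14 with age, with 16 as the highest other and 3 of 10 splits as high, and 16 for melatonin, with 15 as the highest other and 1 of 10 as high. For the correlation of the 2 tables' changes the real size was 0.973 and the highest other 0.970, with 1 of 10 as high.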
